A study of Mus musculus with 2 samples.

How the data were processed

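DNase-seq was measured in 2 libraries of left cerebral cortex from adult male mice aged 18 to 20 months, per the labels. The strain, B6CASTF1/J, is an F1 hybrid between a C57BL/6 laboratory strain and the wild-derived strain CAST. DNase-seq cuts the DNA of isolated nuclei with the enzyme DNase I and sequences the cut ends, so that stretches of open chromatin collect many cuts. Nuclei were isolated by a protocol that the labels link to without describing it. The labels call the libraries biological replicates 1 and 2 and give them separate tissue samples but the same donor entry, so it is not stated whether 2 animals were used. The spread between the libraries may therefore be technical.

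For each library the authors deposited 2 peak lists, a list of footprints and a list of bases with their false discovery rate, all on the mouse build mm10 per the file headers and accompanying notes. Peaks and footprints were called by the authors in each library separately, from that library's own filtered alignments, per the deposited notes. The aligner, the peak caller, the footprint tool, their versions and the thresholds are not given in the sources used here. The deposited signal of a peak is 1 value per peak, and how it was scaled is not stated. Within a library the peak signals below 500 steps (83.2% and 93.2% of the main peaks) were whole multiples of a single step to within 0.05 of a step, with a step of 0.00660 in replicate 1 and 0.00667 in replicate 2, so the 2 scales were nearly equal. The peak signal is the authors' own value and is used to describe and rank peaks, and to set the shared peaks of the 2 libraries side by side. The per-base values that the authors deposited are q-values (false discovery rates), listed where they were at most 0.05. The score in the deposited footprint lists was the same in every row and was not used as a measurement. Reads of both parental genomes were set against a reference built from C57BL/6J, so a peak on a diverged CAST allele can be missed, and no allele-specific values were analysed here.

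The shorter peak list of each library was taken as its main list and the longer, wider list as an alternative. Against the per-base q-values, 99.8% of the main peaks in both libraries held a listed base, and in all of these the best base was at or below a false discovery rate of 0.001. In the wider list the best base reached 0.0499 in replicate 1 and 0.0500 in replicate 2. All peaks lay inside the chromosomes of GRCm38.p6, the reference build used here, and 1 peak in each main list touched an assembly gap. Chromosomes 1 to 19, X and Y were used. Read totals were not used here, so depth is known only through the number of calls, and no counting interval is given.

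Overlaps, shuffles and gene assignments were computed in python 3.11.15 with numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The overlap of peak sets had been planned with another program and was computed with the same rule in this code. A peak was shared when at least 1 bp of it overlapped a peak of the other library. Chance overlap came from 20 shuffles of the peaks of replicate 2 on their own chromosomes, outside assembly gaps, and the chance share of each kind of location from 5 such shuffles. Correlations used the log2 peak signal over peaks that overlapped one to one. Genes and transcription start sites (TSS) came from the GENCODE M21 basic annotation, with 21800 protein-coding genes of unique symbol. A promoter peak lay within 1 kb of a TSS of a protein-coding gene, and a distal peak lay more than 1 kb from every annotated TSS. Of 478 gene entries in 22 lists, 6 had no protein-coding match (Clec7a, H19, Meg3, Rian, Mirg and Kcnq1ot1), and 5 genes stood in 2 lists (Gfap, Ttr, B2m, Igf2 and Des).

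The gene lists, the motif sequences, the tests of these lists and motifs and most of the alternatives were fixed before the data were examined; the exceptions are named where their results are given. For each list the share of members with a promoter peak was placed among 10000 random gene lists of the same size, matched on the decile of the observed over expected CpG content within 500 bp of the TSS. The number of distal peaks per 100 kb of gene body with 10 kb on each side was treated in the same way, as a median over the list's members, with matching on gene length. A list was called high at percentile 98 or above in both libraries and low at percentile 2 or below in both. The percentiles describe these libraries and are not p-values, since genes are not replicates. For 27 motif consensus sequences, sites centred in footprints were counted against 100 random placements of windows of the same width in the same peaks outside footprints. Only footprints wholly inside a main peak and with room for such windows were counted. These were 175032 of 264450 footprints in replicate 1 and 266095 of 385637 in replicate 2. A motif was called when the count lay above, or below, all 100 placements in both libraries. With 2 libraries in 1 group, no test between groups was possible, and values are given per library or as mean ± SD over n = 2.

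The named genes follow a rule fixed at the same time. For each list they are the 2 members with the highest mean promoter signal and up to 2 members, in alphabetical order, without a promoter peak in the main list of either library. Some of the latter had a promoter peak in a wider list. To these come the 10 genes with the strongest promoter peaks, the 10 genes of at least 20 kb with the most distal peaks per 100 kb, the 5 strongest shared distal peaks, and the 5 strongest promoters found in a single library for each library. Only members with a promoter peak in at least 1 library were taken as strongest members, a restriction added after the values were seen. Some genes that the rule names are not reported here. Other named genes or windows are said to have been chosen after their values were seen.

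The steps were tested on simulated data. A planted overlap of 60.0% of 5000 simulated peaks was recovered as 60.0%. Over the 21800 genes, 94.0% of 100 simulated lists with lowered promoter openness were called low and 2.00% of 100 unchanged lists were called either way. For distal peaks, 98.0% of 100 simulated lists with raised density were called high and 1.00% of unchanged lists were called. In 20000 simulated footprints with 200 planted AP-1 sites, 227 sites were found, and 41 sites of the unplanted GATA motif lay between the lowest (35) and highest (64) of 100 placements.

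Alternatives were the strongest 50% of the peaks, the same number of strongest peaks in both libraries, the wider peak list, autosomes alone, a reciprocal overlap of 50%, promoter distances of 500 bp and 2.5 kb, gene bodies alone or with 50 kb on each side, random lists without matching, scrambled motif sequences, footprints in shared peaks, and leaving out each replicate. The GC content of a peak was measured over 200 bp at its centre. Intervals on differences of signal came from 200 bootstrap draws of shared peaks at the 95% level. Those on ratios of AP-1 density came from as many draws of each library's own peaks, taken separately. The latter ignore that many regions are in both libraries. Such intervals cover the spread over peaks, not over animals.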

Results

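Open chromatin was profiled in the left cerebral cortex of aged male F1 hybrid mice (18 to 20 months) as 2 DNase-seq libraries of a single group. The design holds no second condition. The comparisons it allows are where the accessible regions lie, which genes and cell types they mark, which factors' sites fall in footprints, and how far the 2 libraries agree. Replicate 1 had 73221 peaks covering 13.9 Mb (0.509% of the genome, median width 180 bp). Replicate 2 had 111105 peaks covering 23.6 Mb (0.866%, median width 200 bp), for a mean of 92163 per library. Footprints, short protected stretches inside open chromatin, numbered 264450 and 385637, with median widths of 10 and 9 bp. The deposited peak signal had a median of 1.24 in replicate 1 and 0.894 in replicate 2, with maxima of 59.5 and 66.2.

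Accessible regions in the cortex were concentrated at promoters. Of the peaks, 30.7% in replicate 1 and 20.7% in replicate 2 lay within 1 kb of a protein-coding TSS (25.7% ± 7.04, SD, n = 2), 13 and 8.76 times the share of shuffled peaks. Introns held 33.4% and 39.1% of the peaks and intergenic sequence 27.7% and 32.6%, all below the shuffled shares (42.1% and 42.0% for introns, 49.9% and 50% for intergenic sequence). A promoter peak was found for 13222 of 21800 protein-coding genes (60.7%) in replicate 1 and 13340 (61.2%) in replicate 2. Both libraries had one at 12789 genes and neither at 8027. Promoter peaks followed CpG content, from 2.75% and 4.86% of genes in the lowest CpG decile to 96.4% and 95.1% in the highest. The X chromosome, present as a single copy in males, carried 0.379 and 0.396 times the autosomal number of peaks per Mb. Its median signal was 0.779 against 1.25 on autosomes in replicate 1 and 0.547 against 0.901 in replicate 2.

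The strongest promoter peak belonged to Hjurp, a chaperone of centromeric histone, at chromosome 1, 88277541 to 88277760, across the gene's TSS, with a signal of 25.9 ± 1.17 (SD, n = 2). The next were the predicted gene Gm21887 on chromosome X (15.6 ± 6.30), Rsph1, which encodes a protein of motile cilia (14.9 ± 0.143), and Acin1, involved in RNA splicing, which shared its peak with 1700123O20Rik (14.6 ± 1.33). Ankhd1 (14.6 ± 0.577), Bahcc1 (14.4 ± 3.60), the vesicle transport gene Rab11b (14.3 ± 3.24), the RNA-binding gene Hnrnpc (13.7 ± 0.528) and the dynein light chain gene Dynlt1b (13.6 ± 2.72) completed the 10 strongest. The values of Acin1, Ankhd1, Bahcc1 and Rab11b lay within their SDs of each other. The 4 strongest shared distal peaks had higher mean signals than any of these promoters. The strongest shared distal peak lay in intergenic sequence on chromosome 6, 49236441 to 49236600, 21564 bp from the nearest TSS, that of Igf2bp3, with a signal of 40.5 ± 7.12. A peak at 123461921 to 123462080 on chromosome 9, in an exon outside coding sequence and 16705 bp from the TSS of Limd1, had 39.4 ± 10.1. An intergenic peak on chromosome 3 (5860361 to 5860530), 109640 bp from Gm8797, had 33.5 ± 16.7, and an intronic peak 2421 bp from the TSS of Il31ra had 32.3 ± 0.616. The fifth, near Pak3 on chromosome X, had 37.2 in replicate 1 and 13.6 in replicate 2. No list of regions prone to mapping artefacts was used here, so mapping artefacts were not ruled out for any of these promoter and distal peaks. The doubt includes the peaks at Gm21887, near Gm8797 (12.4% repeat sequence) and near Pak3 (22.1% repeat sequence).

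Strong accessible regions were found in both libraries, and the longer list of replicate 2 held many weak ones without a partner. Of the peaks of replicate 1, 85.8% (62844) overlapped a peak of replicate 2, and 56.1% (62319) of the peaks of replicate 2 overlapped one of replicate 1 (mean 71.0%). These shares are the same overlap set against lists of different length, so their SD of 21 (n = 2) is not a spread between replicate measurements. Shuffled peaks overlapped at 1.79% and 1.15%. With the same number of strongest peaks in both libraries the shared parts were 75.8% and 74.9%, and 17696 and 18387 peaks were found in a single library. In the weakest decile of peaks the shared part was 62.3% in replicate 1 and 9.05% in replicate 2, and in the strongest decile it was 99.7% in both. Over 58995 peaks that paired one to one, the log2 signals of the libraries correlated with a Pearson r of 0.81 and a Spearman rho of 0.79 (across peaks, which are not independent replicates). Among these pairs 86.9% agreed to within 2-fold, and the SD of the log2 difference was 0.65.

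**Figure D1:**
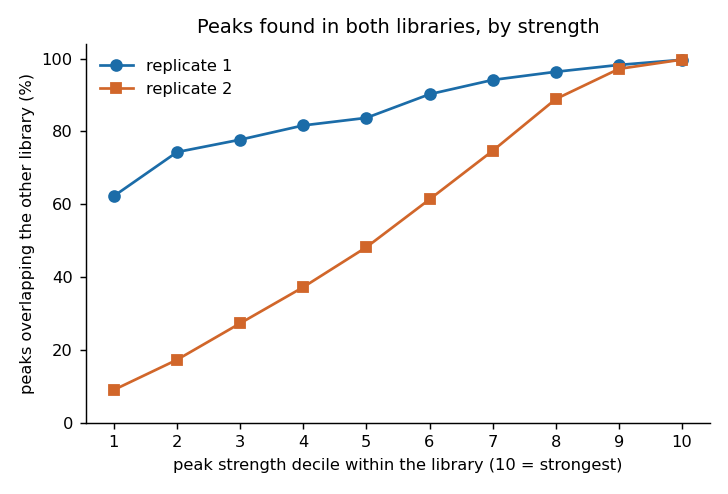
Share of a library's peaks that overlap a peak of the other library (vertical axis, %) for each decile of its peaks ranked by deposited signal (horizontal axis, 10 is the strongest). Circles are replicate 1 and squares replicate 2; the share rises from 62.3% and 9.05% in the weakest decile to 99.7% in the strongest decile of both.

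Peaks found in 1 library differed in kind between the libraries. Replicate 1 had 10377 such peaks, of which 35.4% lay at promoters, and replicate 2 had 48786, of which 9.09% lay at promoters; among shared peaks the share was 30.0% and 29.9%. Their median signals, 0.759 and 0.581, were below the 1.40 and 1.39 of shared peaks, and 50.1% and 41.3% of them overlapped the wider list of the other library. Promoters with a main-list peak in a single library were few, 433 genes in replicate 1 and 551 in replicate 2. The strongest of these in replicate 1 were Nptx1, a neuronal pentraxin (signal 3.11), Mex3d (2.98), Pbx2 (2.76), Ppp4r1 (2.72) and Nfic (2.49). In replicate 2 they were Mst1 (3.51), the histone gene Hist1h2bh (3.31), Pdcd1 (3.02), Arhgef25 (2.88) and the receptor kinase gene Tyro3 (2.80). All 10 had a promoter peak in the wider lists of both libraries.

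The libraries also differed by the GC content of the peaks. Shared promoter peaks had a median log2 difference (replicate 1 minus replicate 2) of 0.29 (95% interval 0.28 to 0.29) and shared distal peaks one of 0.00 (-0.02 to 0.01), over 16438 and 40069 peaks. In bins of GC content both kinds followed the same course. At 45 to 50% GC the medians were -0.24 for promoter and -0.16 for distal peaks, and at 70% GC or more they were 0.60 and 0.57. Below 45 to 50% GC the medians turned up again, to 0.11 and 0.13 at 35 to 40% GC and to 0.40 in 226 distal peaks below 35% GC. Within bins of GC content the promoter minus distal difference was -0.04 (-0.06 to -0.02). Distal peaks found only in replicate 2 had a mean GC content of 46.5%, below the 50.7% of its shared distal peaks.

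**Figure D2:**
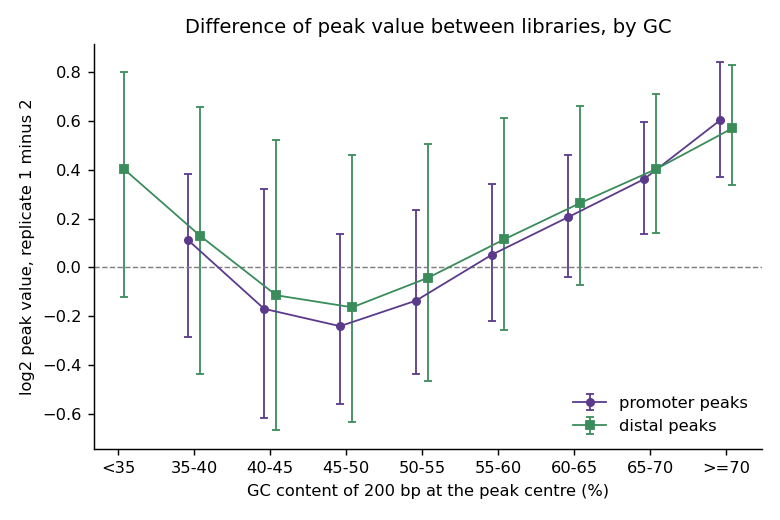
Median difference of log2 peak signal, replicate 1 minus replicate 2 (vertical axis), of shared promoter peaks (circles) and shared distal peaks (squares) in bins of GC content over 200 bp (horizontal axis, %). Bars span the middle 50% of peaks and bins with under 20 peaks are left out; both kinds lie near -0.2 at 45 to 50% GC and near 0.6 at 70% GC or more.

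Promoters of pan-neuronal and excitatory neuron genes were mostly open, and those of Hox, midbrain, hindbrain, germ cell and gut genes were mostly without peaks. Against random lists of the same CpG content, 7 of the 22 gene lists were called low and 0 were called high. The immediate early and housekeeping lists could not be called high here, since every member open still left them below percentile 98. Of the pan-neuronal genes 19 of 20 had a promoter peak in both libraries (percentiles 97.4 and 97.52), led by the synapsin gene Syn2 (4.97 ± 0.992). Excitatory neuron genes had a promoter peak in 17 of 20 members in each library (percentiles 86.5 and 86.1). Camk2a, a kinase of excitatory synapses, had a signal of 4.28 ± 0.0109 at chromosome 18, 60925481 to 60925700 in replicate 1, and Nrgn 4.13 ± 0.117. The transcription factor genes Fezf1 and Fezf2 had none in the main lists, though Fezf2 had a promoter peak in the wider lists of both libraries. Inhibitory neuron genes were called low, with 10 and 11 of 20 members (random median 80%). This call was lost in the wider peak list, an alternative chosen after seeing the data, with 80% of members in both libraries (percentiles 21.2 and 22.9), and without matching on CpG content (percentiles 16.9 and 28.7). Maf (2.01 ± 0.255) and Adarb2 (1.62 ± 0.665) were the strongest of them, and the homeobox genes Dlx1 and Dlx2 had no promoter peak.

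Among glia, oligodendrocyte genes had promoter peaks in 15 and 14 of 20 members (percentiles 98.2 and 89.3), with Olig1 at 2.02 ± 0.406 and Myrf, a regulator of myelin genes, at 1.91 ± 1.38, and none at Aspa or Opalin. With the same number of strongest peaks in both libraries, the shares were 75% and 40% (percentiles 98.2 and 3.2). Much of the share in replicate 2 thus came from its weaker peaks. Oligodendrocyte precursor genes had them in 8 of 15 members in each library (percentiles 6.89 and 6.71). Sox8 (3.76 ± 0.35) and Pdgfra (2.27 ± 1.38) led this list, and Bcas1 and Cacng4 had none. Astrocyte genes had them in 12 and 15 of 20 (percentiles 47.3 and 96.1). With the same number of strongest peaks their shares were 60% and 45% (percentiles 47.3 and 7.94). Glul, the glutamine synthetase gene, had 3.71 ± 0.0908 and Aldoc 2.61 ± 0.0542, while Aldh1l1 and the intermediate filament gene Gfap had none in either library. Microglia genes had 5 of 20 in each library (percentiles 43.6 and 32.0), with Irf8 at 1.58 ± 0.377 and none at the complement genes C1qa and C1qb.

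Vascular genes were called low in the main peak lists. Endothelial genes had promoter peaks in 6 and 4 of 20 members (random median 55%), with the glucose transporter gene Slc2a1 at 3.18 ± 1.1 and Mfsd2a at 1.65 ± 0.128, and none at Cdh5 or Cldn5. Mural and fibroblast genes had 6 of 20 in each library (random median 55%), with Col1a1 at 2.86 ± 0.662 and Des at 1.45 ± 0.256, and none at Abcc9 or Acta2. In the wider peak list both calls were lost, with 45% and 30% of endothelial genes (percentiles 3.20 and 0.02) and 50% and 55% of mural and fibroblast genes (percentiles 8.94 and 17.9). Choroid plexus and ependyma genes had 3 and 6 of 16 (percentiles 2.34 and 48.4). Foxj1, the regulator of motile cilia, was the strongest at 5.43 ± 0.665, followed by Ccdc153 at 1.32 ± 0.369, and Aqp1 and Calml4 had none.

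Of 3 lists for other regions of the nervous system, 2 were called low. Hox genes, which pattern the hindbrain and spinal cord, had a promoter peak at 1 of 31 members in replicate 1 (Hoxa10, signal 1.47) and 0 in replicate 2, where matched random lists had a median of 83.9%; Hoxa11 was among the 30 with none. Midbrain, hindbrain and cerebellar genes had 4 and 2 of 22 (random median 72.7%), with Cbln3 at 1.71 ± 0.235 and the serotonin synthesis gene Tph2 at 0.939 ± 0.0910, and none at En1 or Fev. Striatal neuron genes had 10 and 12 of 16 (percentiles 4.13 and 32.3). With the same number of strongest peaks their shares were 62.5% and 43.75% (percentiles 4.13 and 0.24). Pde10a (4.42 ± 0.0443) and Rgs9 (4.22 ± 1.66) led this list and Drd2 and Six3 had none, though Drd2 had a promoter peak in the wider lists of both libraries.

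Of the 5 lists of other organs and germ cells, 2 were called low. Germ cell genes had 1 of 21 in each library, Dazl at 2.04 ± 0.744, with none at Acr or Bmp15 (random median 42.9%). Gut and pancreas genes had 1 and 3 of 22 (random median 40.9%), with Lgr5 at 1.27 ± 0.131 and Cela1 with a signal of 0.888 in replicate 2 alone, and none at Amy2a5 or Cdh17. Liver genes had 1 and 2 of 22 (random median 18.2%, percentiles 4.27 and 8.76), with Apob at 2.16 ± 0.682 and Ttr at 0.5005 in replicate 2 alone, and none at Ahsg or Alb. Within 500 bp of a TSS no liver gene had a peak in either library, and the list was called low (percentiles 1.16 and 0.62). Blood and lymphoid genes had 2 and 3 of 26 (random medians 15.4% and 19.2%, percentiles 8.40 and 13.7), with Epor at 2.57 ± 0.176 and none at Alas2. Muscle genes had 3 and 8 of 22 (random medians 27.3% and 31.8%, percentiles 3.02 and 78.1), with Mylpf at 4.98 ± 2.28, Des as above, and none at Acta1 or Actc1.

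All 20 immediate early genes and all 25 housekeeping genes had promoter peaks in both libraries (percentiles 93.4 and 94.4, and 94.5 and 96.3). With every member open, these were the highest percentiles that these lists could reach against the matched random lists. The AP-1 subunit genes Jun (9.26 ± 0.142) and Jund (7.31 ± 2.04) led the immediate early genes, and the ribosomal gene Rplp0 (11.1 ± 0.30) and Vcp (8.40 ± 1.70) the housekeeping genes. Imprinted genes had 26 of 31 in each library (percentiles 48.7 and 53.2), with Inpp5f at 6.93 ± 2.40 and Ube3a at 6.29 ± 1.68 and none at Ddc or Dlk1. Genes of ageing and glial reactivity had 12 and 14 of 23 (percentiles 88.4 and 98.3), with the antigen presentation genes H2-D1 (7.16 ± 2.85) and B2m (3.99 ± 0.784) the strongest and none at the complement gene C3 or the chemokine gene Ccl4. With random lists not matched on CpG content, 15 lists were called (5 high, 10 low).

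**Figure D3:**
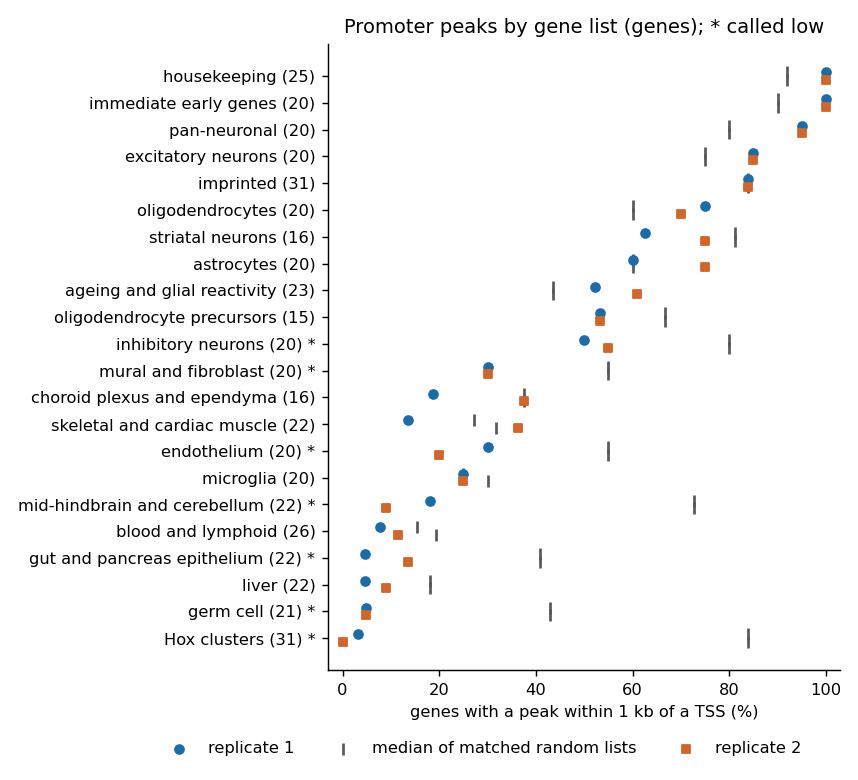
Share of the genes of each list with a peak within 1 kb of a TSS (horizontal axis, %) in replicate 1 (circles) and replicate 2 (squares), with list sizes in parentheses. Grey ticks are the medians of random lists matched on CpG content and asterisks mark the 7 lists called low; Hox genes lie at 3.23% and 0% against a random median of 83.9%.

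Distal accessible regions were denser around pan-neuronal, immediate early, astrocyte and imprinted genes than around random genes of the same length. These 4 lists were called high and 0 were called low. Pan-neuronal genes had a median of 5.18 and 7.58 distal peaks per 100 kb (6.38 ± 1.70, SD, n = 2; random medians 1.96 and 3.54), immediate early genes 6.48 and 8.30 (7.39 ± 1.28), astrocyte genes 3.69 and 6.87 (5.28 ± 2.25) and imprinted genes 3.84 and 5.90 (4.87 ± 1.45). Oligodendrocyte genes, at 3.78 and 5.52, had percentiles of 97.69 and 97.97 and missed the call. Excitatory neuron genes, at 2.80 and 5.62 (percentiles 86.4 and 98.5), and microglia genes, at 2.86 and 7.06 (percentiles 84.4 and 99.9), passed percentile 98 in replicate 2 alone, and muscle genes, at 4.36 and 4.12 (percentiles 99.2 and 90.5), in replicate 1 alone. Midbrain, hindbrain and cerebellar genes had 0.920 and 0.432 (percentiles 20.4 and 0.72). The other 13 lists lay between percentiles 25.3 and 96.9 in both libraries. The astrocyte and imprinted calls were lost with 50 kb on each side of the gene, and the astrocyte call without matching on length. A distal peak counted for every member whose window held it. Neighbouring members of a list could therefore share peaks, which was not corrected for. Calls from replicate 2 alone numbered 7.

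The 10 genes with the most distal peaks mostly differed between the libraries; over all genes the median was 1.71 distal peaks per 100 kb in replicate 1 and 3.16 in replicate 2. Atp1b1, a sodium pump subunit gene on chromosome 1, had 55.8 distal peaks per 100 kb in replicate 2 and 4.85 in replicate 1 (30.3 ± 36.0, SD, n = 2). Gabbr1, a GABA receptor gene (46.8 and 4.07), Igsf8 (42.2 and 5.12) and the thyroid hormone receptor gene Thra (39.3 and 12.4) also had more in replicate 2, and Dnm1, a dynamin of synaptic vesicle recycling, had 35.5 and 17.0, a ratio near that of all genes. The neighbouring genes Nfic and Celf5 on chromosome 10 had more in replicate 1 (51.6 and 50.6 against 5.03 and 9.20), as had B4galt5 on chromosome 2 (41 against 8.48). Adgrb1 (25.7 ± 3.03) and Trim7 (22.8 ± 1.53) were dense in both libraries.

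CTCF sites were the most enriched in footprints over background windows of the same peaks in both libraries. By mean ratio NFI, EGR and RFX sites followed, in an order that differed between the libraries and with the background used. Of 27 motifs, 13 lay above all background placements in both libraries and 5 below. CTCF, an architectural protein, had 4539 and 4682 sites centred in footprints, 208 and 118 times the background (mean 163 ± 63.6, SD, n = 2). NFI sites, bound by nuclear factor I proteins, were 54.2 and 25.4 times the background (39 and 44 sites), EGR sites 25 and 43.4 times, and RFX sites 23.2 and 35.8 times. The NFI ratios rest on few background sites, 0 to 3 per placement in replicate 1 and 0 to 4 in replicate 2. Against scrambled sequences NFI had ratios of 12.2 and 10.6 and RFX 97.6 and 146. CRE/ATF sites were 22.9 and 31.8 times the background, NRF1 sites 16.6 and 29.8 times and SP/KLF sites 8.96 and 11 times. The NEUROD motif, bound by neuronal bHLH factors, had 2921 and 5565 sites at 4.44 and 6.01 times, and ZBTB33 (3.85 and 5.53), YY1 (4.34 and 3.32), ETS (1.91 and 3.09), AP-1 (1.51 and 3.38) and CEBP (1.60 and 3.07) were also above.

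The 5 motifs below the background of the same peaks were GATA, PU.1, the POU octamer, homeodomain and RUNX. GATA sites, bound by factors of blood and endothelium, were 0.386 and 0.328 times the background, PU.1 sites, bound by a factor of myeloid cells and microglia, 0.519 and 0.599 times, POU octamer sites 0.465 and 0.682 times, homeodomain sites 0.521 and 0.805 times and RUNX sites 0.871 and 0.862 times. SOX, HNF4 and ROR sites lay within the range of the placements in both libraries, and HNF1 and p53 had 0 sites in the counted footprints. REST sites were above in replicate 1 alone (7.95 times, 26 sites) and in both libraries with footprints in shared peaks or with scrambled sequences; MEF2 sites (3.75 times, 270 sites) and myogenic bHLH sites (3.05 times, 24 sites) were above in replicate 2 alone, and TEAD sites were below in replicate 1 alone (0.673 times). The counted footprints had a GC content of 62.9% and 58.7% against 54.6% and 51.7% in their background windows. With scrambled motif sequences as the background, CEBP fell below the mean of the scrambles (mean ratio 0.663) and its call was lost. The calls of EGR (3.25), CRE/ATF (10.7), ZBTB33 (15.4) and AP-1 (6.37) were lost at mean ratios above 1, since 1 to 3 of the 100 scrambles had as many sites. SP/KLF has too few letter orders for this background, which then contains the motif itself. None of the 5 calls below held in that setting, in which GATA, PU.1, homeodomain and RUNX were not called and the POU octamer turned to above (mean ratio 3.83), and the RUNX call was also lost with footprints in shared peaks alone.

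**Figure D4:**
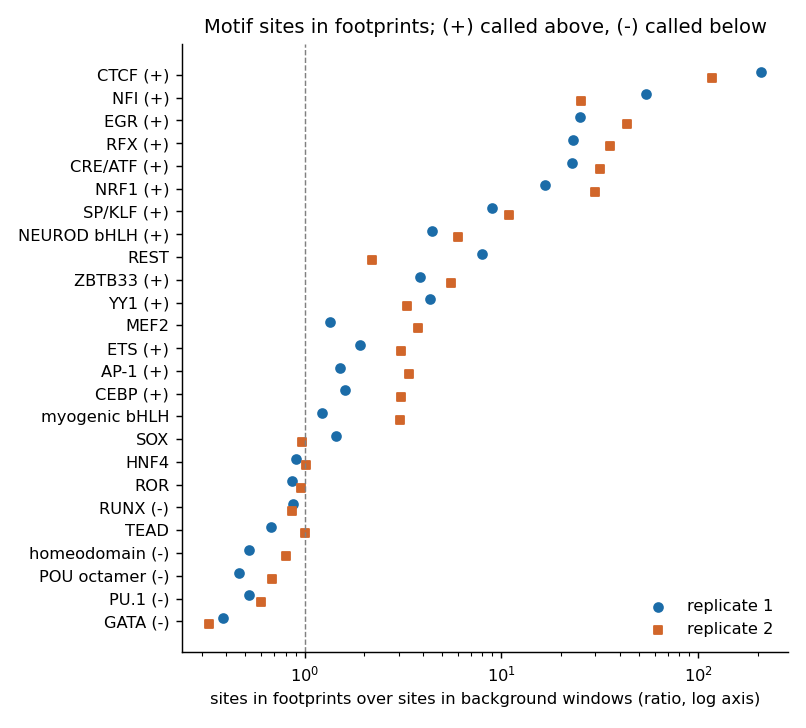
Number of motif sites centred in footprints divided by the mean number in background windows of the same peaks (horizontal log axis) for replicate 1 (circles) and replicate 2 (squares). Plus signs mark the 13 motifs above all 100 placements in both libraries and minus signs the 5 below. CTCF lies at 208 and 118 and GATA at 0.386 and 0.328. HNF1 and p53, without sites in the counted footprints, are not drawn.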

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

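Protected and accessible stretches also appeared outside the peak lists, in data that no comparison above uses, and no explanation was tested for them. In replicate 1, 21008 footprints lay outside both of its peak lists, and in replicate 2, 34981 did. Bases listed at a false discovery rate of at most 0.05 outside both lists came to 12.4 Mb in replicate 1 (35.9% of its listed bases) and 22.3 Mb in replicate 2 (37.1%). No control libraries were used here, so these values stand against a count of 0.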

How the results depend on the processing

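The wider peak list for promoter lists and for the correlation, and both settings that moved the number of single-library peaks, were chosen after seeing the data. With the strongest 50% of the peaks the mean number per library was 46081, and in the wider lists 149290, by construction. The correlation between the libraries was 0.79 for the same number of strongest peaks (r = 0.789) and as a rank correlation (rho = 0.787), and 0.840 in the wider lists; the cause was not tested. Promoter lists called went from 7 to 15 without CpG matching (9 gained, 5 high and 4 low, and inhibitory neurons lost; the cause was not tested), and numbered 5 to 9 under the other settings. With distal peaks, 2 lists were called with 50 kb on each side of the gene, and 5 and 7 from a single library (without replicate 2 and without replicate 1), where the rule asks for 1 library in place of both. The POU octamer turned from below to above with scrambled sequences (mean ratio 3.83; the cause was not tested), under which 7 of the 18 motif calls were kept. Single-library peaks numbered 59163, 81416 with a reciprocal overlap, 36083 with the same number of strongest peaks and 101237 in the wider lists, which hold fewer and more peaks by construction. The mean shared share ran from 58.3% to 75.4% and is not judged against its SD of 21, which reflects the list lengths. Mean promoter share (20.2% to 30.7%) moved by less than the spread between the libraries. Where 1 of the 2 libraries is left out, that outcome is fixed in advance. Motifs above background (9 to 15) moved by less than 1.5 times. All 7 promoter calls were kept at 500 bp, at 2.5 kb and with equal numbers of strongest peaks. Each library alone also kept them, which is fixed in advance because a call asks for the limit in both libraries. Without read totals, what depth limits is known only from the weak peaks, most of which in replicate 2 had no partner.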

Other observations

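The comparison of promoter with distal peaks within GC bins, the GC trend among strong promoters, the AP-1 density within GC bins and among distal peaks, and the peak-crowded windows were chosen after the results were seen; the other tests were set out before. Some stretches of the genome were crowded with peaks. Of windows of 100 kb, 16 in replicate 1 and 37 in replicate 2 held at least 25 peaks, and 10 did in both. A window on chromosome 11 (69000001 to 69100000) with the clock gene Per1, the synaptic gene Vamp2 and Aurkb held 42 and 35 peaks, and the histone cluster on chromosome 13 (23500001 to 23600000) held 29 in each. The window with Nfic and Celf5 on chromosome 10 (81400001 to 81500000) held 61 peaks in replicate 1, of median signal 0.449, and 14 in replicate 2, of median signal 1.76. The window with Ptgis and B4galt5 on chromosome 2 held 41 peaks of median signal 0.191 in replicate 1 and 9 of median signal 1.45 in replicate 2. In the other direction, the window on chromosome 1 with Igsf8 and the glial potassium channel gene Kcnj10 held 12 peaks of median signal 2.49 in replicate 1 and 44 of median signal 0.931 in replicate 2.

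Promoter peaks leaned to replicate 1 relative to distal peaks, by 0.29 on the log2 scale (95% interval 0.28 to 0.30). A difference of sequencing depth, which scales all peaks of a library alike, would need this to vanish among strong peaks, and there it was -0.0319 (-0.06 to -0.003). The same strong promoter peaks, however, ran from -0.15 at 50 to 55% GC to 0.53 at 70% GC or more, a difference of 0.68 (0.65 to 0.73), which a common scaling forbids and which argues against depth alone. Within GC bins the lean was -0.0385, which leaves GC content as a candidate explanation, found and tested on the same peaks. Restricting to strong peaks (signal of at least 2 in both libraries) removed the lean as well. There promoter peaks had a median of 0.28 and distal peaks one of 0.31, against 0.00 for all shared distal peaks. GC content and peak strength were not separated as explanations of the lean. No biological explanation was tested.

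AP-1 sites were denser in the peaks of replicate 2 than in those of replicate 1, 0.618 against 0.437 per kb of peak, a ratio of 1.42 (95% interval 1.38 to 1.46), and in distal peaks of a single library 0.951 against 0.271. The larger number of weak peaks and the smaller share of promoter peaks in replicate 2 were each too little as the whole cause, since the ratio was 1.32 (1.28 to 1.37) with the same number of strongest peaks and 1.25 (1.21 to 1.28) among distal peaks. Within GC bins the ratio over all peaks was 1.18 (1.14 to 1.22), where GC content and promoter share were not separated. Among distal peaks alone it was 1.202 (1.165 to 1.250) within GC bins, against 1.25 without them, with overlapping intervals. With the same number of strongest peaks as well, the distal ratio within GC bins was 1.18 (1.13 to 1.21). These ratios argue against GC content, as binned here, as the whole cause. The ratio over all peaks within GC bins, however, lay between the bounds chosen for a verdict either way, so by those bounds it was undecided. Whether GC content accounts for part of the ratio is left open. Within GC bins, shared distal peaks with an AP-1 site (5312) differed from the other 34757 by -0.46 (-0.49 to -0.45) in the log2 difference of replicate 1 minus replicate 2. Their signal thus leaned to replicate 2 relative to the others, past the bound set beforehand against GC content. That bound concerns signal and does not decide on the number of sites. No biological explanation was tested.

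Distal peaks near oligodendrocyte genes leaned to replicate 1 (median log2 difference 0.47 over 38 peaks) and those near pan-neuronal genes to replicate 2 (-0.21 over 105 peaks), which might come from different shares of oligodendrocytes and neurons in the tissue samples. Against 1000 random lists matched on gene length the lists lay at percentiles 91.9 and 10.5, inside the limits of 98 and 2, and at 93.0 and 12.9 after subtracting the median of each GC bin. GC content and a different share of cell types cannot be told apart here, because neither list left a pattern of distal signal beyond the random lists to explain. Inhibitory neuron genes had a median of 0.37 (percentile 93.0, and 97.3 after the GC step) and excitatory neuron genes one of -0.08 (percentile 45), and differences between lists were not tested. Of the 22 lists, mural and fibroblast genes (0.64 over 25 peaks) and Hox genes (0.84 over 11 peaks) lay above percentile 98 before the GC step, and mural and fibroblast genes at 99.0 after it.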
